A study of Macaca fascicularis with 12 samples.

How the data were processed

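Single-nucleus RNA sequencing libraries from the hippocampus of crab-eating macaques were analysed: 12 libraries in 4 groups of 3. Young and aged monkeys had received a control vector, AAV-BRI, or a vector that carries BRI joined to Aβ42, AAV-BRI-Aβ42. The groups are named BRI_young, BRI_aged, Abeta_young and Abeta_aged, from the sample titles. The treatment tags of the 6 Aβ samples run from Aβ42 to Aβ47 in steps of 1, while their titles give Aβ42 throughout, and the titles were used. The titles number the libraries 1 to 3 in each group, and the labels do not say which animal or which side of the brain a library comes from.

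The values used are UMI counts per gene and barcode. The deposited count matrices were made with Cell Ranger 7.2.0, per the file headers, with no later filtering: each holds 2889210 to 4140422 barcodes and the same 21027 genes, of which 16199 carry a symbol. The submitters' processing notes name Seurat 3.1.3. Per the labels' protocols, the authors used DynamicEX 1.0.3 with the Ensembl Macaca_fascicularis_5.0 reference, DoubletFinder 2.0.2 and Harmony 0.1, kept nuclei with at least 200 genes and at most 5% mitochondrial counts, and removed free RNA. The counts read here precede those steps. How the counted features relate to the vector sequence is not given in the sources used here. Columns of other samples used: 0.

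Nuclei were separated from free RNA in each library. Of all barcodes, 410949 held at least 200 genes. In every library many of these form a plateau of barcodes with similar totals. The UMI minimum was set at the mode of the plateau plus 3 of its spreads, which gave a minimum between 379 and 5825 UMIs. Nuclei over 5% in the 13 mitochondrial genes were left out (12 nuclei), which left 84234 nuclei, 670 to 16820 per library. The 3000 most variable genes, 30 principal components, a Harmony-type correction per library (60 clusters, theta 2) and Leiden clustering (20 neighbours, resolution 1) gave 33 first clusters. Scrublet scored doublets per library. Its automatic threshold called under 0.5% of nuclei in 8 libraries, so the highest-scoring nuclei were called by rank at the expected rate instead, 6169 in all (7.32%; 0.531% to 10% per library). Left out were 2 clusters whose profile correlated above 0.95 with the plateau (10776 nuclei) and 5 clusters with over 20% doublets (4702 nuclei). A second clustering at resolution 1.5 gave 39 final clusters.

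Clusters were named from 146 markers of 18 cell types fixed before the data were examined, 2 of which are not in the files. A cluster took the name of the type whose markers had the highest mean log2 fold over the other clusters. It needed at least 3 of those markers at 20 CPM or more, at most 20% called doublets and a margin of 0.5 over the next type. The name was withdrawn where the cluster's UMIs were low for its class, where its top 10 genes held more markers of another class, or where it shared 3 top genes with a larger cluster of another class. This named 28 clusters in 12 classes. The other 11 clusters, with 11727 nuclei, stayed unnamed. Called doublets inside named classes (2380) were left out, and 54649 named nuclei remained.

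Depth per library, in the order BRI_young 1 to 3, BRI_aged 1 to 3, Abeta_young 1 to 3 and Abeta_aged 1 to 3, is as follows. Total UMIs were 106931504, 21514508, 66979743, 142952431, 64895130, 33711665, 111227693, 33516524, 80200302, 79592595, 88776143 and 81557996. Named nuclei were 4082, 644, 2858, 10934, 1658, 983, 5451, 599, 3424, 7610, 6809 and 9597. The UMI minimum was 2392, 2684, 2338, 659, 4264, 1119, 1796, 5825, 1187, 1301, 529 and 379. Kept nuclei, which are all nuclei left after the background-like and doublet-rich clusters were removed, named or not, held 52.5, 39.5, 59.5, 73.7, 56.4, 69.2, 50.4, 45.5, 36.9, 56.6, 72.7 and 70.8% of a library's UMIs. Over the 12 pairs of libraries within a group, summed counts correlate at 0.878 to 0.991 on the log2 CPM scale, and counts differ by a chi-square of 83.3 to 292 per degree of freedom. The spread between libraries is therefore far above counting error, and the tests take their error from that spread.

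Counts were summed per library and class where a library held at least 20 nuclei of the class, and a class was tested where every group kept at least 2 libraries. This left 7 classes: astrocytes (10 libraries), dentate granule neurons (11), excitatory neurons (11), inhibitory neurons (11), microglia (12), oligodendrocytes (12) and oligodendrocyte precursors (10). BRI_young 2 lacks the nuclei in 5 of these classes and BRI_aged 3 in astrocytes and precursors. Genes were tested with the edgeR 4.0.16 quasi-likelihood test (TMM scaling, filterByExpr, 1 mean per group) in R 4.3.3, with Benjamini-Hochberg adjustment within a class and a threshold of 0.05. The contrasts are Aβ against BRI and aged against young, each over both levels of the other factor and within each level, and their interaction. All adjusted p-values for genes come from that test unless a sentence names another. CPM values are means over libraries of the class sums, with the SD. Log2 folds come from the fit, with their SE.

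Gene lists, 29 with 768 genes, were written before the data were examined. Camera (limma 3.58.1, preset correlation 0.01) tested each list with at least 5 members in each class, with Benjamini-Hochberg adjustment over all 203 pairs of list and class in a contrast. Camera with an estimated correlation and fry were the alternatives. Shares of named nuclei were tested with an exact permutation test, two-sided, over 400 arrangements within the strata of the other factor. Its smallest possible p is 0.005. The lists, markers, tests, contrasts and first alternatives were all fixed before the data were examined. The rule for nuclei, the rank-based doublet calls and the background-like clusters were settled on the count distributions before any group was compared.

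Genes are named by a rule fixed before the data were examined. For the contrasts over both levels it takes the 12 largest folds up and down among passing pairs of gene and class with a symbol, at least 20 CPM and the same sign at both levels of the other factor, at most 4 per class. For the other contrasts it takes 5 in each direction. Where nothing passes, the 5 smallest p-values are named as not passing. From each called list 4 members with the smallest p are named, and 2 from a list without a call. This was narrowed to 2 per list in the class with the smallest camera p where the call ends with an estimated correlation, and to the 6 lists with the smallest p for Aβ against BRI. ITM2B, APP, GFAP, APOE and TREM2 are always given. Some genes that the rule picks are not reported here. Genes lower in all 7 classes are named beside the rule, after their values were seen. So are PROX1, TRPC6, CX3CR1 and CAMK2A, markers that differ between libraries of a class, and the mitochondrial transcripts COX1, ND4, ND4L and ND5. Where an aged group holds no count, the fold is a bound from a floor of 3 counts over the group. With 1 to 3 counts in an aged group a ratio of summed counts is given with its exact 95% interval, within the vector concerned. That interval carries counting error only and leaves out the spread between libraries. A fitted fold over both vectors depends on the prior count where 1 group holds so few, which is said beside it.

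Alternatives were DESeq2 1.42.0 in place of edgeR, RLE scaling, no filter on low counts, nuclei with at least 500 genes, at most 1% mitochondrial counts, doublets kept, the replicate number as a block, only the groups of a contrast in the fit, centred log ratios (0.5 nuclei added) for shares, and leaving out each library. Added after seeing the data were: the plateau profile subtracted from the class sums, the 3 libraries with under 50% of UMIs in kept nuclei left out, and, per class, libraries left out whose own markers have a geometric mean under 0.5 of the median over libraries. Below, libraries under 50% in nuclei always means those 3, by their share of UMIs in kept nuclei. The scripts were tested on simulated data drawn from the real means and library sizes, with known changes, before the real fits. Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and leidenalg 0.10.2 did the rest. Left out were barcodes under the UMI minimum, background-like clusters, clusters rich in doublets, called doublets and classes with too few nuclei. Unnamed clusters entered only as shares. Genomic coordinates are not given, since no annotation of this genome build was used here.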

Results

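The data are UMI counts from 12 single-nucleus libraries of crab-eating macaque hippocampus, 3 for each pairing of age (young, aged) with vector (AAV-BRI, AAV-BRI-Aβ42). They hold 599 to 10934 named nuclei each and median totals from 2635.5 to 13149 UMIs per named nucleus. The comparison of aged with young libraries asks which genes and cell classes differ with age. The comparison of Aβ with BRI asks what the Aβ42 cargo adds to the BRI protein that both vectors carry, and the interaction asks whether that differs with age. P-values of camera with the preset correlation set the members of a list against the other genes and rest on that assumed correlation. Those of the gene and share tests measure the spread between these libraries. The labels call them biological replicates but do not say which animal or side each comes from. The 7 classes tested come from the same 12 libraries, so a gene that moves in several classes was not seen in independent samples.

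ITM2B (ENSMFAG00000036817), the BRI gene, and APP (ENSMFAG00000002479), the source of the Aβ sequence, come first because both relate to the vectors. In excitatory neurons ITM2B stood at 172.4±85.9 CPM in BRI_young (n=2), 110.2±25.8 in BRI_aged (n=3), 222.9±75.5 in Abeta_young (n=3) and 83.8±33.2 in Abeta_aged (n=3). APP stood at 713.5±149.8, 737±94.4, 700.2±50 and 706.4±25.8 CPM in the same order. Aβ against BRI gave a log2 fold of -0.01±0.27 for ITM2B and -0.04±0.12 for APP, both with adjusted p = 1. ITM2B was at -1.03±0.27 in aged against young, where adjusted p = 0.0706 does not pass, and APP at 0.03±0.12. Counts of ITM2B and APP check the labels only as far as the counted part of each gene is on the vector, which was not settled here. Neither gene separates the vectors.

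**Figure D1:**
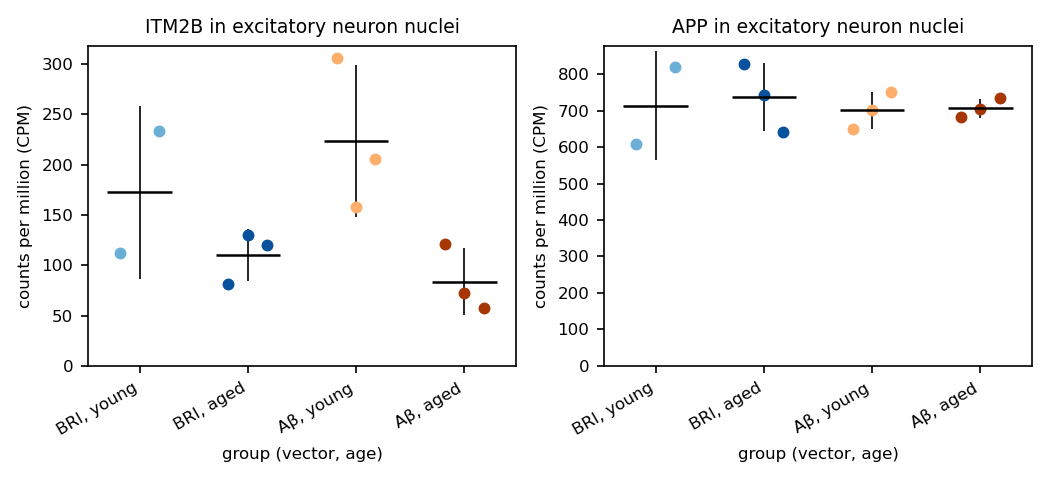
ITM2B and APP in excitatory neurons of each group, in CPM. Dots are libraries, the line is the mean and the bar the SD, stopped at 0.

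T or NK cells took a smaller mean share of aged libraries and oligodendrocytes a larger one. T or NK cells made up 10.95±9.89% of named nuclei in young and 0.361±0.622% in aged libraries (n=6 each, exact permutation p = 0.010, adjusted p = 0.04). By group they stood at 10.7±10.6% in BRI_young, 0.604±0.887% in BRI_aged, 11.2±11.5% in Abeta_young and 0.118±0.0621% in Abeta_aged. The spread among young libraries is wide, from 0.334% in Abeta_young 2 to 23.2%, and Abeta_young 2 and BRI_young 1 (1.54%) lie below BRI_aged 3 (1.63%). Oligodendrocytes rose from 28.1±10.8% (14.6 to 45.3%) to 54.1±13.8% (35.0 to 74.4%; exact permutation p = 0.010, adjusted p = 0.04). Ependymal cells fell from 1.08±0.857% to 0.119±0.0590% (exact permutation p = 0.005, adjusted p = 0.04). B or plasma cells (4.94±9.55% young, 0.144±0.229% aged, adjusted p = 0.075), vascular cells (1.91±1.23% and 0.401±0.147%, adjusted p = 0.096) and perivascular macrophages (8.49±9.12% and 1.94±4.34%, adjusted p = 0.23) did not pass. BRI_young 2 holds 24.4% B or plasma cells and the other young libraries 0.167 to 2.28%, and without it the difference goes from -4.80 to -0.852 percentage points, and that of macrophages from -6.55 to -3.53. Microglia were at 8.44% in young and 7.51% in aged libraries (exact permutation p = 0.83). With centred log ratios microglia turn to higher with age (1.40, adjusted p = 0.036 from the exact permutation test) and inhibitory neurons are called higher too (adjusted p = 0.036). No class passed for Aβ against BRI, and the smallest p was that of ependymal cells, 0.285±0.268% in BRI and 0.916±0.992% in Aβ (exact permutation p = 0.025, adjusted p = 0.3). Shares depend on the UMI minimum, from 379 to 5825 between libraries, since small nuclei such as lymphocytes are lost first at a high minimum. In 5 of 6 aged libraries it was 379 to 1301 UMIs, in BRI_aged 2 it was 4264, and in young libraries it was 1187 to 5825. Without the 3 libraries with under 50% of their UMIs in kept nuclei, BRI_young 2, Abeta_young 2 and Abeta_young 3, the differences with age are -7.10 percentage points for T or NK cells (-10.59 with them), 18.8 for oligodendrocytes (26.04) and -0.933 for ependymal cells (-0.963). None passes there, with adjusted p = 0.15, 0.24 and 0.15 from the exact permutation test over 40 arrangements. Leaving out 1 library moves the differences between -7.59 and -13.3 for T or NK cells, 22.4 and 30.1 for oligodendrocytes and -0.772 and -1.18 for ependymal cells. With 200 arrangements the 3 classes still pass without BRI_young 1 or without Abeta_young 2, and without any other library their adjusted p is 0.06 to 0.14. Unnamed clusters held 22.9±13.6% of the nuclei in BRI_young, 9.54±8.05% in BRI_aged, 31.7±26.7% in Abeta_young and 3.38±0.904% in Abeta_aged, and are outside these shares.

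**Figure D2:**
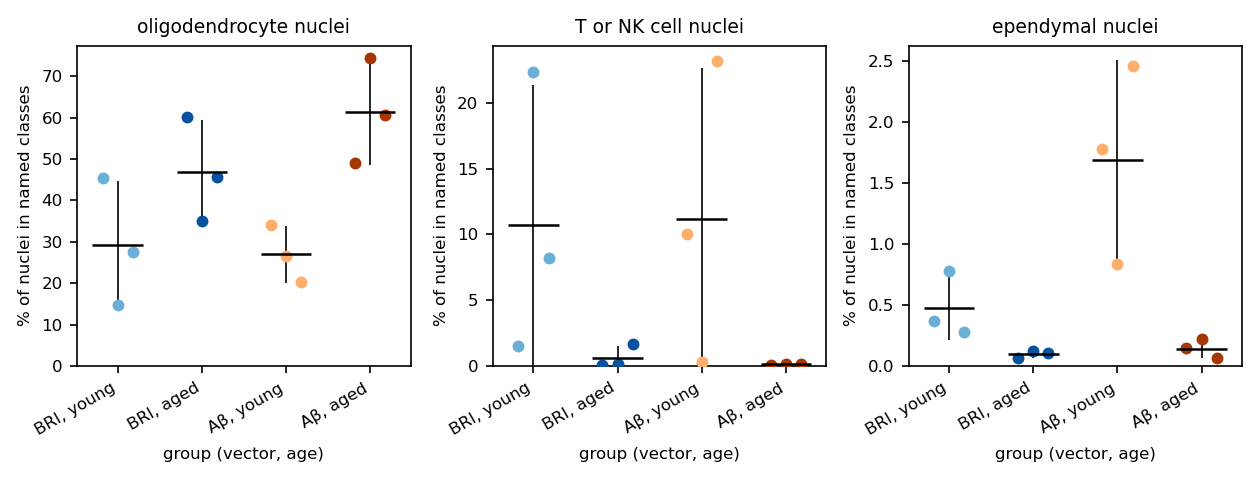
Share of named nuclei per class and group. Dots are libraries, the line is the mean and the bar the SD, stopped at 0.

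Interferon genes were lower in aged than in young hippocampus in every class tested. DDX60 (ENSMFAG00000016136), an RNA sensor partner, fell in astrocytes from 111.2±36.9 CPM (n=5) to 3.88±4.96 (n=5), a log2 fold of -5.88±0.44 (adjusted p = 0.000179), with 2 counts in BRI_aged. It fell in precursors by 4.84±0.29 on the log2 scale (119.2±58.1 to 4.12±2.37 CPM, adjusted p = 2.7e-06) and in oligodendrocytes by 6.15±1.02 (154.8±120.6 to 4.19±8.58, adjusted p = 0.00595). Inhibitory and excitatory neurons gave -5.16±0.35 (50.7 to 1.35 CPM, adjusted p = 3.48e-05) and -4.83±0.40 (39.3 to 1.3, adjusted p = 0.000461). In each of these 5 classes every aged library lay below every young one. Abeta_young 2, the young library with the smallest T or NK share, is among those above all aged libraries.

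The interferon list holds 42 genes, 37 of them in the files and none in another list. In astrocytes 28 of its 33 measured members fell, 32 adjusted over the list alone, at a median log2 fold of -3.51. In precursors 22 of 29 fell (29 adjusted over the list alone, median -2.65), in inhibitory neurons 19 of 33 (29, median -2.08), in excitatory neurons 23 of 37 (30, median -2.23), in microglia 18 of 33 (30, median -2.05) and in granule neurons 14 of 32 (25, median -2.53). No member rose in any class. Camera called the list lower in all of these with both correlations: the adjusted p with an estimated correlation is 0.00268 in astrocytes, precursors and inhibitory neurons, 0.00213 in excitatory neurons, 0.0479 in microglia and 0.0236 in granule neurons. In oligodendrocytes all 36 measured members fell, at a median of -4.28 (camera adjusted p = 6.61e-63), yet the call ends there, with adjusted p = 0.0984 with an estimated correlation. MX1, a GTPase that blocks viruses, gave -5.91±0.51 in astrocytes (111.1 to 2.64 CPM, adjusted p = 0.000296, with 2 counts in BRI_aged) and -6.08±1.02 in oligodendrocytes (166.5 to 3.14). In precursors it went from 65.4 to 0.991 CPM, with no count in BRI_aged, at least 31.7-fold lower than in BRI_young.

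Further interferon genes fell class by class. IFIT3 went from 47.3±4.95 to 3.30±0.73 CPM in astrocytes (-3.74±0.23, adjusted p = 7.99e-05). IFI44 went from 83.6 to 1.64 CPM in precursors (adjusted p = 0.000156), with no count in BRI_aged, and its relative IFI44L from 191.4 to 5.84 (-4.91±0.35). IFI6, a mitochondrial protein that interferon induces, gave -4.08±0.32 in astrocytes and -3.21±0.30 in inhibitory neurons. EPSTI1 gave -3.87±0.33 in granule neurons and -3.05±0.24 in inhibitory neurons, and TRIM22, an antiviral ubiquitin ligase, -2.97±0.24 in excitatory neurons. PARP14, an ADP-ribosyltransferase, fell by 2.65±0.18 in precursors and by 5.90±0.91 in oligodendrocytes (290.3 to 6.42 CPM, adjusted p = 0.00482), where APOL2 fell by 6.11±0.92 (92.2 to 2.23, adjusted p = 0.0044). In microglia GBP1, a GTPase of cell defence, fell from 173.1 to 7.59 CPM (-4.61±0.52), IRF1, a transcription factor, from 51.3 to 5.53 (-3.13±0.30) and STAT2 from 196.5±34.5 to 66.5±7.99 (-1.55±0.15, adjusted p = 0.00126). CXCL10, the chemokine that draws T cells, fell in microglia from 77.3 to 1.05 CPM (adjusted p = 0.00126), with count ratios of 43.5 in BRI (95% interval 14.7 to 212) and 106 in Aβ libraries (35.4 to 520). Such intervals, here and below, hold counting error only and not the spread between libraries. In astrocytes CXCL10 stood at 72.5±51.6 CPM in young libraries and had no count in any of the 5 aged ones, at least 172-fold lower (adjusted p = 0.0303).

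Antigen presentation genes moved the same way. The list holds 34 genes, 22 of them in the files and 4 of the 34 in another list. In microglia 14 of its 21 measured members fell (18 adjusted over the list alone, median -1.93), in precursors 10 of 15 (14, median -3.67), in inhibitory neurons 9 of 21 (18, median -2.40), in excitatory neurons 7 of 20 (18, median -2.32) and in granule neurons 6 of 19 (16, median -2.65). The adjusted p with an estimated correlation is 0.0225, 0.00939, 0.0321, 0.0479 and 0.0225 in that order. In astrocytes 11 of 19 fell (19 adjusted over the list alone) and in oligodendrocytes 17 of 21 (20), but those calls end, with adjusted p = 0.0984 and adjusted p = 0.0997 with an estimated correlation. NLRC5 (ENSMFAG00000032845), the activator of class I genes, fell in precursors from 167.9±65.4 to 1.93±1.19 CPM (-6.39±0.29, adjusted p = 3.93e-07, all 5 aged libraries below all 5 young, with 3 counts in BRI_aged). It also gave -5.51±0.55 in excitatory, -5.14±0.52 in inhibitory and -5.42±0.52 in granule neurons. CIITA, the activator of class II genes, fell in microglia from 286±83.5 to 45.01±19.9 CPM (-2.67±0.31, adjusted p = 0.00224) and in precursors, where the count ratio in BRI libraries is 20.9 (95% interval 5.37 to 179). TAP1, the peptide transporter, fell in inhibitory neurons by 3.64±0.28 (35.4 to 2.72 CPM), in excitatory by 3.29±0.36, in granule neurons by 2.72±0.36 and in microglia by 2.86±0.43. PSMB9 and PSMB8, subunits of the immunoproteasome, gave -2.56±0.28 and -2.42±0.29 in microglia, and PSMB9 -2.67±0.26 in inhibitory neurons. B2M, the class I light chain, gave -3.67±0.44 in precursors, -2.92±0.37 in excitatory and -3.23±0.44 in granule neurons. HLA-E gave -4.17±0.34, -3.69±0.26, -3.18±0.27 and -3.59±0.35 in precursors, excitatory, inhibitory and granule neurons. Class I genes have many near copies, so the HLA-E counts are uncertain.

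Across the 7 classes 2139 of 86927 pairs of gene and class passed with age, 565 higher and 1574 lower, from 1450 distinct genes. Oligodendrocytes gave 312 higher and 777 lower, excitatory neurons 87 and 132, precursors 93 and 183, astrocytes 9 and 196, microglia 34 and 123, inhibitory neurons 22 and 102 and granule neurons 8 and 61. Inhibitory neurons are led by cluster 24 in the young groups and cluster 20 in the aged. DESeq2 called 2357 higher and 3432 lower. Of these genes 20 were lower in all 7 classes, among them STAT2, NLRC5, B2M, TAP1, HLA-E, HLA-F, BTN3A2, DDX60, EPSTI1, IFI6, PARP14, APOL6, IDO1, IL21R, PLAC8, GFAP and SERPINA3. The interferon and antigen presentation lists hold 10 of the 20. GFAP is a marker of astrocytes, yet it fell in the neuron classes too. Whether free RNA or mixed nuclei carry such genes into other classes was not tested for the genes outside those 2 lists. HLA-F and BTN3A2 have close relatives, and their counts are as uncertain as those of HLA-E. Leaving out 1 library moves the total between 888 (without Abeta_aged 2) and 3707 (without Abeta_young 2), so the number of genes is uncertain. Direction under the alternatives was followed for the named genes only.

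**Figure D3:**
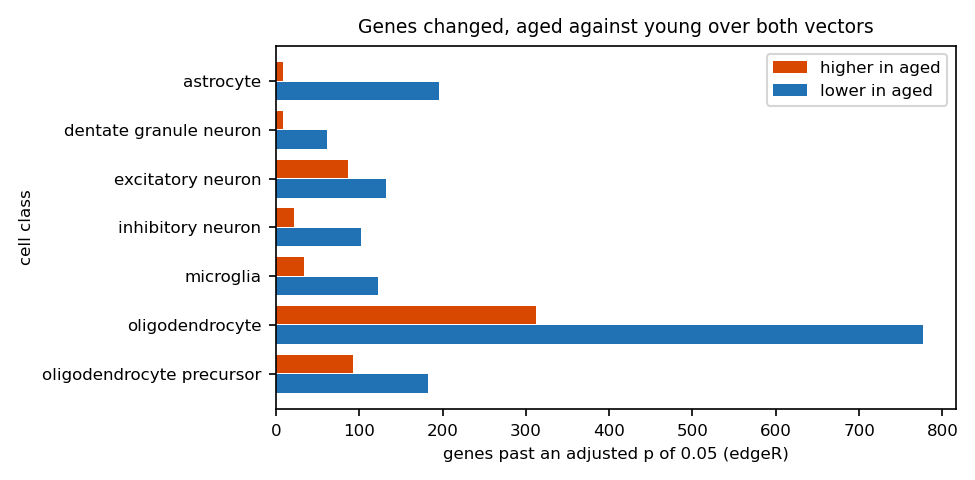
Genes that passed in each class for aged against young over both vectors, higher and lower in aged.

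Reactive astrocyte genes were lower with age. GFAP (ENSMFAG00000042945), the astrocyte filament, fell in astrocytes from 589.3±245.3 to 83.2±32.2 CPM (-2.81±0.41, adjusted p = 0.00768, all 5 aged libraries below all 5 young). SERPINA3, a secreted protease inhibitor, fell from 209.4±178.1 to 2.39±1.81 (-6.47±1.08, adjusted p = 0.016) and CHI3L1, a glycoprotein of inflamed glia, from 52.6±30.7 to 3.90±5.17 (adjusted p = 0.00768), with a count ratio of 56 in BRI libraries (95% interval 18.8 to 274). The reactive astrocyte list has 30 genes, 9 shared with other lists, and 13 of its 21 measured members fell in astrocytes (19 adjusted over the list alone, median -2.29). Camera called it lower in all 7 classes (adjusted p = 2.03e-24 in astrocytes), which ends everywhere, with adjusted p = 0.216 with an estimated correlation in astrocytes. The stress-associated oligodendrocyte list (20 genes, 12 of them in other lists) was called lower in all 7 classes. Its smallest p was in astrocytes (adjusted p = 8.58e-07, adjusted p = 0.348 with an estimated correlation), where 4 of 14 fell, 7 adjusted over the list alone. Those moved there include SERPINA3 and B2M (65.9±32.4 to 2.00±1.09 CPM, -4.91±0.48), which belong to other lists as well, so the name of the list does not describe them. In oligodendrocytes themselves 5 of 15 fell, 5 adjusted over the list alone (adjusted p = 0.00145, adjusted p = 0.384 with an estimated correlation).

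Markers of immune cells fell inside the oligodendrocyte class. CD3D, a T cell receptor chain, went from 4.73±5.98 to 0.0322±0.0430 CPM there, and its summed counts give a ratio of 65.2 (95% interval 21.4 to 324; adjusted p = 0.00595). TRAC, another receptor chain, fell from 13.7±13.5 to 0.419±0.345 (-5.03±0.87, adjusted p = 0.00695). Of the T and NK list (20 genes, none in another list) 12 of 16 measured members fell, 15 adjusted over the list alone, with a median of -3.96 (camera adjusted p = 3.53e-14, adjusted p = 0.314 with an estimated correlation). The list was called lower in all classes but astrocytes. Complement genes ITGAM (-2.36±0.32, 13.2 to 2.54 CPM) and ITGB2 (-2.86±0.44, 7.89 to 1.04), integrin chains of myeloid cells, fell in oligodendrocytes with 5 of 12 members, 7 adjusted over the list alone (adjusted p = 3.47e-07, adjusted p = 0.216 with an estimated correlation). In microglia that list of 22 genes, 3 shared, was not called (adjusted p = 0.121). INPP5D, a lipid phosphatase of blood cells, gave -2.67±0.38 (24.0 to 3.78 CPM) and ABI3 -2.0±0.34 in oligodendrocytes, where 6 of 27 members of the Alzheimer disease risk list fell, 9 adjusted over the list alone (31 genes, 6 shared; adjusted p = 0.000824, adjusted p = 0.372 with an estimated correlation). It was not called in microglia (adjusted p = 0.634). The homeostatic microglia list (16 genes, 12 in the files, 2 shared) was lower in oligodendrocytes with 4 of 12 members, 7 adjusted over the list alone (adjusted p = 0.000386, adjusted p = 0.244 with an estimated correlation). ENTPD1 (-2.22±0.52, 57.1 to 12.6 CPM) and MEF2C (-0.77±0.18, 105.1 to 62.0) are examples, and MEF2C turns to 0.16 when free RNA is subtracted. In microglia the same list was higher with 1 of 12 members passing, 2 adjusted over the list alone (adjusted p = 0.0475, adjusted p = 0.573 with an estimated correlation). Cytokine and NF-kB genes (23, 2 shared) were lower in oligodendrocytes with 7 members falling and 1 rising of 14, or 11 and 1 adjusted over the list alone (adjusted p = 4.82e-08, adjusted p = 0.297 with an estimated correlation). CXCL10 has count ratios there of 76.7 in BRI (95% interval 25.6 to 378) and 364 in Aβ libraries (99.3 to 3020), and CASP1, which cleaves cytokine precursors, fell by 3.51±0.50. In microglia 2 of 15 fell, 7 adjusted over the list alone (adjusted p = 0.000401, adjusted p = 0.172 with an estimated correlation). The oligodendrocyte class also differs in its clusters, with cluster 1 leading in Abeta_young (20.99%) and cluster 11 in the other groups (25.7 to 35.3%). Of kept nuclei without called doublets, cluster 1 held 1.985 and 3.68% in BRI_young and Abeta_young. It held 0.504 and 0.0298% in BRI_aged and Abeta_aged. Cluster 19 held 3.93 and 3.87% against 0.707 and 0.0807%. Clusters 0, 2, 5, 10 and 11 of the class held larger shares in both aged groups. Age in this class thus compares different mixes of clusters, and what that contributes was not tested. The plateau profile of free RNA makes up a median of 19.8% of the counts of oligodendrocytes (5.52 to 36.7%) and 29.1% of those of microglia.

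Microglial genes linked to plaques did not rise with age. The plaque-associated list (23 genes, 8 shared) was called lower in all 7 classes. In microglia none of 21 members passed at either level (median -0.60, adjusted p = 0.0317, adjusted p = 0.778 with an estimated correlation). In astrocytes 2 of 19 fell, 13 adjusted over the list alone (adjusted p = 1.75e-08, adjusted p = 0.385 with an estimated correlation): CSF1, a growth factor for microglia (-1.63±0.31, 20.2 to 6.94 CPM, adjusted p = 0.0284), and MYO1E, a motor protein (-1.17±0.25, 204.0 to 86.7, adjusted p = 0.0493). APOE, a lipid carrier, stood in microglia at 341.4±236.6 CPM in young and 167.4±56.5 in aged libraries (-1.0±0.42, adjusted p = 0.299). TREM2, a lipid receptor, stood at 239.3±51.7 and 153.9±65.0 (-0.67±0.23, adjusted p = 0.205).

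Lists of protein synthesis and folding genes leaned lower with age under the preset correlation. Cytosolic ribosomal proteins (50 genes, 35 in the files, none shared) were called lower in all 7 classes. Transcripts of the mitochondrial genome fell as well, COX1 in 6 classes, ND4 in 5 and ND4L and ND5 in 4 each, and how much cytoplasmic RNA the nuclei carry was not measured. In granule neurons 1 of 35 fell and 30 did adjusted over the list alone (median -1.04, adjusted p = 1.2e-22, adjusted p = 0.314 with an estimated correlation). RPL27 passed there (-1.34±0.24, 15.9 to 6.29 CPM, adjusted p = 0.0494), and RPL4 did not (-1.22±0.24, adjusted p = 0.0634). The unfolded protein response list (28 genes, 3 shared) was called lower in all 7 classes and most strongly in inhibitory neurons, with 3 of 26 falling and 8 adjusted over the list alone (adjusted p = 1.58e-10, adjusted p = 0.308 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, fell there from 36.7±9.35 to 12.8±5.41 CPM (-1.45±0.26, adjusted p = 0.0245) and CALR, a calcium-binding chaperone, by 1.2±0.24. The heat shock list (28, 5 shared) was lower in astrocytes with 0 of 22 members passing, 4 adjusted over the list alone (adjusted p = 0.021, adjusted p = 0.646 with an estimated correlation). HSP90B1 at -1.23±0.32 and CRYAB at -1.57±0.42 stand nearest to passing. Senescence and DNA damage genes (26, 2 shared) were lower in astrocytes with 2 of 17, 5 adjusted over the list alone (adjusted p = 1.75e-05, adjusted p = 0.396 with an estimated correlation). They were GADD45B, a stress sensor (-2.09±0.42, 13.5 to 3.91 CPM), and FAS, a death receptor (17.8 to 1.33; count ratio 13.9 in BRI libraries, 95% interval 3.48 to 121). Both also answer to inflammatory signals. Endothelial barrier genes (20, 2 shared) were lower in astrocytes with 2 of 14, 3 adjusted over the list alone (adjusted p = 0.0263, adjusted p = 0.385 with an estimated correlation). ICAM1 (-3.10±0.67, 21.8 to 2.57 CPM) and VCAM1 (20.5±14.6 to 0.351±0.786, count ratio 82.8, 95% interval 22.6 to 689; no count in Abeta_aged, at least 25.8-fold lower than in Abeta_young) are adhesion molecules that inflamed cells also make. Of the genes named as fallen with age over both vectors these 2 alone overlap between the ages, with 4 of 5 aged libraries below all young for ICAM1 and 0 for VCAM1. The precursor proliferation list (20, 5 shared) was lower in precursors with 0 of 15 passing, 1 adjusted over the list alone (adjusted p = 0.0302, adjusted p = 0.645 with an estimated correlation). ENPP6 at -1.42±0.38 and BCAS1 at -1.15±0.37, both genes of maturing oligodendrocytes, did not pass.

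Genes higher with age were fewer. MYO5C (ENSMFAG00000033683), a motor of secretory vesicles, rose in precursors from 15.3±5.72 to 86.0±20.2 CPM (2.34±0.23, adjusted p = 0.000156, 5 of 5 aged libraries above all young). SLC22A2, a transporter of organic cations, rose there from 31.3±15.6 to 185±114.5 (2.47±0.39, adjusted p = 0.0057, 5 of 5). In oligodendrocytes CMTM8, a membrane protein, rose from 4.96 to 52.6 CPM (3.16±0.81, adjusted p = 0.0383, 5 of 6) and VSTM4, a receptor-like protein, from 12.7 to 69.8 (2.39±0.51, adjusted p = 0.0182, 5 of 6). In excitatory neurons RXFP1, the relaxin receptor, rose from 75.4±106.2 to 358.8±217 (3.16±0.65, adjusted p = 0.0467), CCDC60 from 16.9 to 104.5 (3.05±0.51, adjusted p = 0.0237) and GRM8, a glutamate receptor, from 76.5 to 429.6 (2.80±0.51, adjusted p = 0.0328), each in 4 of 6 aged libraries above all young. The excitatory class differs in its clusters: cluster 27 leads in BRI_young (33.6%) and Abeta_young (48.4%), cluster 17 in BRI_aged (30.2%) and cluster 6 in Abeta_aged (36.3%). CAMK2A, a marker of the class, stands at 224 to 283 CPM in BRI_aged 1 and 3 and Abeta_aged 2 and 3, against 459 to 719 in the other libraries tested. RXFP1 also rose in astrocytes, from 15.5 to 136.7 CPM (3.13±0.68, adjusted p = 0.049, 3 of 5). It is among the top genes of the unnamed clusters 9 and 21, whose best type is excitatory neuron. In microglia 4 of the genes named by the rule rose: CRHBP, a binding protein of a stress hormone (2.09±2.88 to 41.5±28.8 CPM, adjusted p = 0.00867, 6 of 6, with 1 count in Abeta_young), CDH13 (60.6 to 1041, 4.13±0.75, 5 of 6), CACNG2 (12.98 to 108.1, 2.83±0.46, 6 of 6) and KCNIP1 (27.9 to 261.4, 2.63±0.53, 6 of 6). The microglial marker CX3CR1 stands at 1.60 CPM in BRI_aged 3, against 230 to 321 in the other aged libraries and 12.9 to 273 in the young. Whether free RNA or mixed nuclei carry CRHBP, CDH13, CACNG2 and KCNIP1 into microglia, or RXFP1 into astrocytes, was not tested. These rises are therefore not assigned to the glial cells themselves.

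Gene lists called higher with age held few members that passed. GABA signalling (22, 1 shared) was higher in astrocytes with 0 of 21, also 0 adjusted over the list alone (adjusted p = 0.000532, adjusted p = 0.578 with an estimated correlation): GABRG3 at 0.45±0.20 does not pass. Presynaptic genes (31, 1 shared) were higher in astrocytes with 0 of 31 (adjusted p = 0.00333, adjusted p = 0.766 with an estimated correlation), UNC13B at 0.48±0.17 and VAMP1 at 0.92±0.33. So were calcium and potassium channels (33, none shared) with 0 of 30 (adjusted p = 0.038, adjusted p = 0.822 with an estimated correlation), CACNA2D3 at 0.86±0.45. Myelin genes (20, 1 shared) were higher in inhibitory neurons with 0 of 18 (adjusted p = 0.00198, adjusted p = 0.636 with an estimated correlation), OPALIN at 1.16±0.35 and FA2H at 0.97±0.36. In oligodendrocytes 2 of 18 rose, and 4 rose and 1 fell adjusted over the list alone (adjusted p = 0.00569, adjusted p = 0.667 with an estimated correlation). Cholesterol synthesis (23, none shared) was higher in oligodendrocytes with 1 of 21 members rising, 0 adjusted over the list alone (adjusted p = 0.00701, adjusted p = 0.648 with an estimated correlation). MVD, a step of that pathway, rose from 9.20 to 16.2 CPM (0.79±0.20, adjusted p = 0.0407), and INSIG1, its brake, was at 1.25±0.36 (adjusted p = 0.0625). Homeostatic astrocyte genes (20, 2 shared) were higher in precursors with 0 of 15, 2 adjusted over the list alone (adjusted p = 0.00334, adjusted p = 0.172 with an estimated correlation), with the glutamate transporters SLC1A3 at 0.76±0.20 and SLC1A2 at 0.65±0.19. In astrocytes that list was not called (adjusted p = 0.0701). The extracellular matrix list (24, 1 shared) was higher in granule neurons with 0 of 12, and 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.0444, adjusted p = 0.441 with an estimated correlation), with TIMP3 at 3.70±1.06 and FBN1 at -0.93±0.28. That call ends without the libraries low in granule markers (adjusted p = 0.783).

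Granule neurons are not alike in all libraries. PROX1, their defining transcription factor, stands at 0.919, 12.7 and 2.70 CPM in BRI_aged 3, Abeta_aged 2 and Abeta_aged 3, against 126 to 164 in the other libraries. TRPC6, a channel of the same cells, stands at 3.98, 5.45 and 5.39 against 84 to 139. All of these low libraries are aged, so whether their nuclei are granule neurons like the others is uncertain. Every age result given for granule neurons, the interferon, antigen presentation and ribosomal ones included, may compare unlike nuclei. The neurogenesis list (21, 4 shared) was not called in granule neurons (adjusted p = 0.297), where IGFBPL1 was at 1.74±0.66 and DCX, a protein of young neurons, at 2.16±0.94. DCX turns to -0.63 without those libraries. In excitatory neurons no call was made with age for amyloid precursor processing (26 genes, 3 shared; adjusted p = 0.487; ECE1 at 0.93±0.27), oxidative phosphorylation (60, 35 in the files; adjusted p = 0.35), immediate early genes (27, 1 shared; adjusted p = 0.37; NR4A1 at 1.37±0.35 and NPAS4 at 1.83±0.49) or postsynaptic genes (34, 1 shared; adjusted p = 0.213). In the oxidative list NDUFS1, a subunit of complex I, fell from 70.9 to 53.3 CPM (-0.42±0.09, adjusted p = 0.0465), while COX8A at -1.10±0.26 did not pass. In the postsynaptic list LRRTM4, a synapse organiser, rose from 590.3 to 2088 CPM (1.84±0.38, adjusted p = 0.0467), and GRIN1 was at -0.35±0.10. Presynaptic genes in excitatory neurons have a median of -0.10 and a mean of 0.02, and channels a median of 0.01 and a mean of -0.02, both uncalled. In microglia lysosome and autophagy genes (38, 7 shared) were not called (adjusted p = 0.424; ATP6V1H at -0.30±0.13 and ULK1 at -0.44±0.20).

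**Figure D4:**
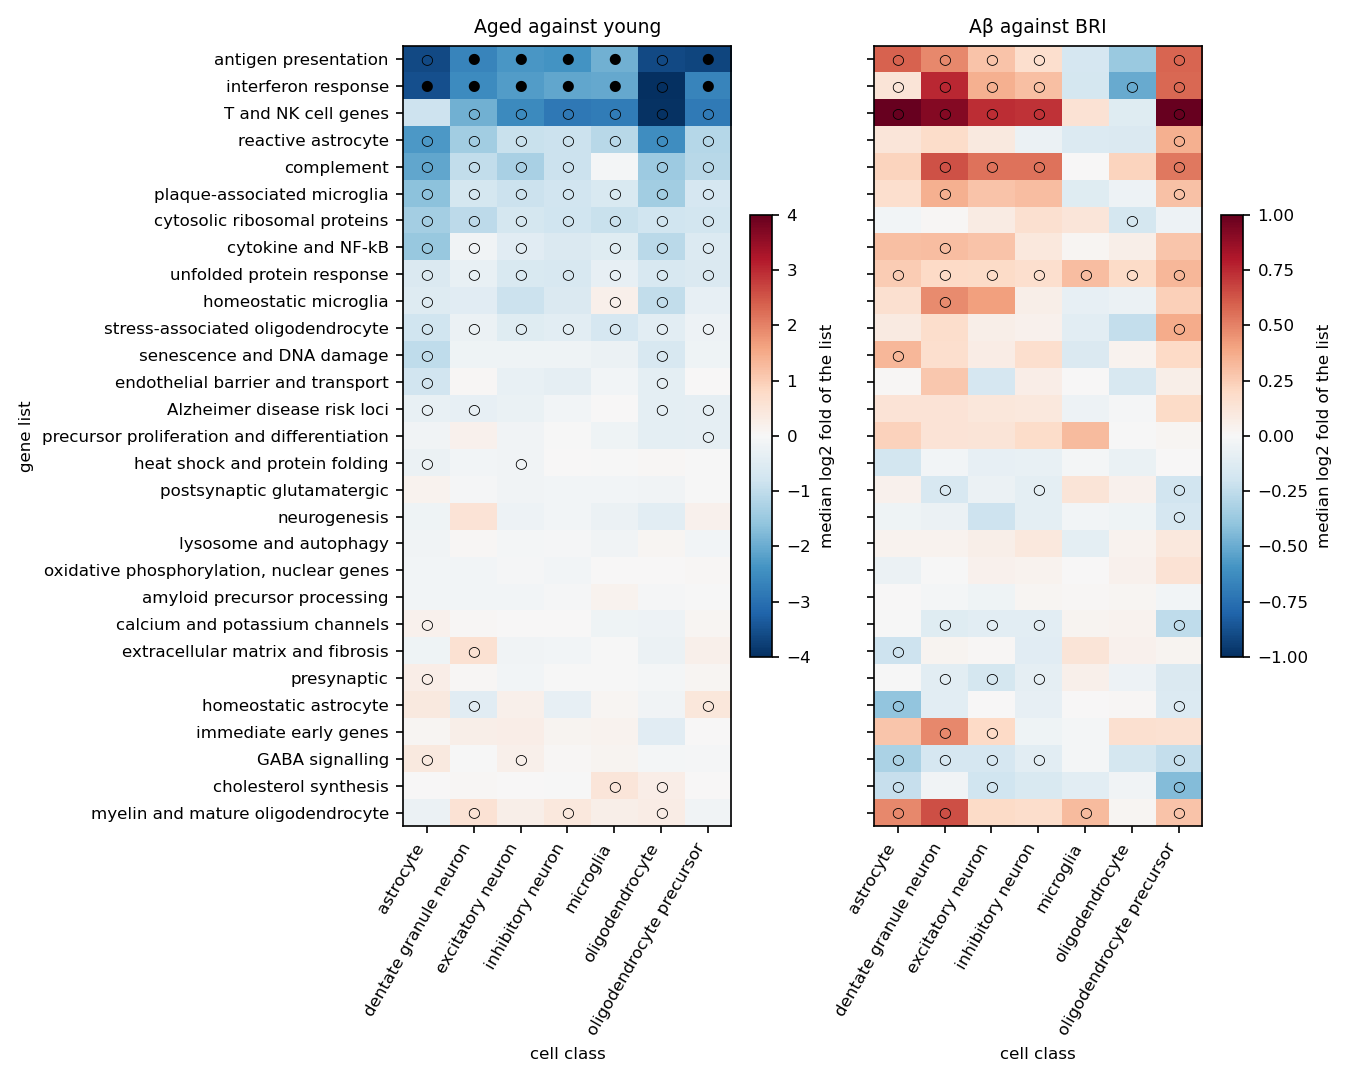
Median log2 fold of each gene list in each class, for age and for Aβ. A filled circle marks adjusted p under 0.05 with an estimated correlation, an open circle with the preset correlation only, and the colours end at ±4 for age and ±1 for Aβ.

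Some of the interferon genes above are also named within each vector, from the same libraries. In BRI libraries 5 pairs of gene and class were higher and 71 lower with age, and in Aβ libraries 221 and 715. NLRC5 fell in precursors of BRI libraries (adjusted p = 0.000107; count ratio 96.5, 95% interval 32.7 to 471). In their astrocytes DDX60 has a count ratio of 150 (41.1 to 1240; adjusted p = 0.00963), MX1 of 153 (42 to 1270; adjusted p = 0.0131) and IFI44 of 109 (19.2 to 4350; adjusted p = 0.0171). In precursors of BRI_aged IFI44 had no count, at least 44.5-fold lower than in BRI_young (adjusted p = 0.016). In oligodendrocytes of Aβ libraries DDX60 fell by 7.82±1.57 (adjusted p = 0.0323), APOL2 by 7.72±1.40 (adjusted p = 0.0272), IFI44 by 7.09±1.64 (adjusted p = 0.0492), MX1 by 6.99±1.5 (adjusted p = 0.0393) and PARP14 by 6.92±1.35 (adjusted p = 0.032). In microglia of BRI libraries CMTM8 rose by 2.9±0.43, PDGFC, a growth factor, by 2.10±0.33, FAM184A by 1.97±0.31 and ZC3H12C, a regulator of RNA decay, by 1.37±0.19 (adjusted p = 0.0409 each), and MYO5C in precursors by 2.03±0.35 (adjusted p = 0.0426). In Aβ libraries RXFP1 (6.16±0.98, adjusted p = 0.0207) and the transcription factor TSHZ2 (5.69±0.93, adjusted p = 0.0222) rose in astrocytes. RXFP1 (5.64±0.94, adjusted p = 0.0335), CCDC60 (4.59±0.72, adjusted p = 0.0287) and TSHZ3 (4.33±0.83, adjusted p = 0.0471) rose in their excitatory neurons. None of these differs between the vectors after adjustment: the interaction of TSHZ2 in astrocytes has adjusted p = 0.959, and those of RXFP1, PDGFC and ZC3H12C have adjusted p = 1.

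No gene passed for Aβ against BRI in any class. Over both ages the edgeR test called 0 of 86927 pairs of gene and class, with 2533 at unadjusted p under 0.05 (1181 higher, 1352 lower) and a smallest adjusted p of 0.784. DESeq2 called 1 higher and 3 lower. In young libraries the counts were 0, 2119 and 13, and in aged libraries 0, 3062 and 20, in that order. Each count at unadjusted p under 0.05 is below the share of 0.05 that unchanged genes would give. None of these counts is therefore read as a sign of change. The smallest p-values, none passing, belong to CNTN5, a neuronal adhesion molecule, in excitatory neurons (436.4±164.8 CPM in BRI, 193.2±47.0 in Aβ, -1.02±0.16, adjusted p = 0.784), COL26A1 (33.7 and 18.2, -1.54±0.25), NFIC, a transcription factor (51.2 and 35.4, -0.51±0.09), and CPNE8 (65.5 and 130.1, 0.98±0.18) in the same class, and SAMD3 in granule neurons (1.80 and 5.26, 1.54±0.27). In young libraries they belong to ADAMTS16, a matrix protease, in astrocytes (-3.11±0.44, adjusted p = 0.311), COL26A1 (-2.77±0.40, adjusted p = 0.51) and HHATL (-2.81±0.56, adjusted p = 1) in excitatory neurons, and the interferon genes PARP14 (1.2±0.23) and EPSTI1 (1.63±0.34, both adjusted p = 1) in precursors. In aged libraries they belong to CPNE8 (1.49±0.24), CNTN5 (-1.25±0.21), MOXD1 (-2.04±0.36) and IGSF21 (-1.09±0.19) in excitatory neurons (adjusted p = 0.665 each) and CCDC175 in microglia (3.10±0.57, adjusted p = 1). GFAP in astrocytes was at 0.12±0.39, APOE in microglia at 0.18±0.41 (226.0 CPM in BRI, 282.8 in Aβ) and TREM2 at 0.22±0.23 (189.2 and 204.0), all with adjusted p = 1. On simulated libraries with the same depth the edgeR test called 97% of 4-fold changes between Aβ and BRI. Of 2-fold changes it called 65.4% over all classes and 41% in the lowest class. Only genes of at least 20 CPM were changed there, and genes were drawn independently around 1 mean profile per class. Structure that many genes share between libraries is therefore left out, and the power in the real data was not measured.

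Interferon genes leaned higher with Aβ in 5 classes, a pattern that holds only under the preset correlation. Of 203 pairs of list and class camera called 63, 39 higher and 24 lower, and with an estimated correlation 0 (smallest adjusted p = 0.339). With the plateau profile subtracted 16 are higher and 17 lower, and without BRI_young 1 the balance is 14 to 37. In granule neurons 30 of 32 interferon members have a positive fold (median 0.76, adjusted p = 4.15e-13, adjusted p = 0.339 with an estimated correlation). None passes over all genes tested and 3 do adjusted over the list alone. TRIM22 was at 6.86±6.87 CPM in BRI and 27.9±25.3 in Aβ (1.66±0.35), and PARP9 at 5.72 and 15.8 (1.22±0.28). In precursors 27 of 29 were positive (median 0.58, adjusted p = 1.32e-11, adjusted p = 0.339 with an estimated correlation). Astrocytes had a median of 0.13 and a mean of 0.49, with 4 members adjusted over the list alone, excitatory neurons a median of 0.35 with 1, and inhibitory neurons a median of 0.30 with 0. In oligodendrocytes the list was lower (median -0.51, adjusted p = 0.026, adjusted p = 0.926 with an estimated correlation), which turns to higher without the 3 libraries under 50% in nuclei (adjusted p = 0.0062). In microglia it was not called (median -0.18, adjusted p = 0.116). Antigen presentation was higher in the same 5 classes (granule neurons adjusted p = 8.73e-05, adjusted p = 0.53 with an estimated correlation) and uncalled in microglia (adjusted p = 0.451). Outside the interferon list a member passed adjusted over the list alone in only 3 pairs of list and class: reactive astrocyte genes in precursors (1 higher), extracellular matrix in astrocytes (1 lower) and homeostatic astrocyte genes in granule neurons (1 lower, list uncalled).

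Other lists leaned higher with Aβ, all with 0 members passing over all genes tested, and none was called with an estimated correlation. Myelin genes were higher in microglia (median 0.32, adjusted p = 9.9e-06, adjusted p = 0.475 with an estimated correlation), with PLLP at 20.5±6.5 CPM in BRI and 33.0±13.8 in Aβ (0.68±0.32). That call ends without the libraries under 50% in nuclei (adjusted p = 0.109). In oligodendrocytes, the source of myelin, the list was not called (adjusted p = 0.893, median 0.02, mean -0.03). Immediate early genes were higher in excitatory neurons, 18 of 19 with a positive fold (median 0.20, adjusted p = 0.000121, adjusted p = 0.397 with an estimated correlation). The unfolded protein response was higher in all 7 classes (in excitatory neurons adjusted p = 0.000559, adjusted p = 0.708 with an estimated correlation). Complement (adjusted p = 0.000597), T and NK (adjusted p = 0.00121), homeostatic microglia (adjusted p = 0.00236), plaque-associated (adjusted p = 0.00261) and cytokine genes (adjusted p = 0.0398) were higher in granule neurons, each over 0.4 with an estimated correlation. In microglia, where plaque responses are usually sought, none of these was called: complement adjusted p = 0.787, homeostatic 0.79, plaque-associated 0.716 and cytokine 0.757 (median 0.02, mean -0.10). The stress-associated oligodendrocyte list was higher in precursors (adjusted p = 0.0154) and uncalled in oligodendrocytes (0.227). Senescence genes were higher in astrocytes (adjusted p = 0.0289) and reactive astrocyte genes in precursors (adjusted p = 0.0293), the latter uncalled in astrocytes (0.693).

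Synaptic and metabolic lists leaned lower with Aβ, again with 0 members passing over all genes tested. Calcium and potassium channels were lower in precursors (median -0.25, adjusted p = 3.1e-05, adjusted p = 0.596 with an estimated correlation), with CACNA1I at -0.77±0.27. Cholesterol synthesis was lower there too (median -0.43, adjusted p = 7.07e-05, adjusted p = 0.475 with an estimated correlation). LSS, a cyclase of that pathway, stood at 25.3±5.89 CPM in BRI and 15.8±3.83 in Aβ (-0.66±0.25). GABA signalling was lower in precursors (median -0.24, adjusted p = 7.34e-05, adjusted p = 0.429 with an estimated correlation), with GABRA2 at 135.8 and 85.5 CPM (-0.74±0.26) and GABRG3 at -0.38±0.18. Homeostatic astrocyte genes were lower in astrocytes (median -0.40, adjusted p = 8.26e-05, adjusted p = 0.708 with an estimated correlation), with the pump subunit ATP1B2 at -0.75±0.33 and the GABA transporter SLC6A11 at -0.61±0.28. Presynaptic genes were lower in excitatory neurons (median -0.18, adjusted p = 0.000354, adjusted p = 0.397 with an estimated correlation) and postsynaptic genes in inhibitory neurons (adjusted p = 0.000113, adjusted p = 0.716 with an estimated correlation) but not excitatory ones (adjusted p = 0.0589). Ribosomal proteins in oligodendrocytes (adjusted p = 0.00929, adjusted p = 0.913 with an estimated correlation), neurogenesis in precursors (adjusted p = 0.0138, adjusted p = 0.397 with an estimated correlation) and extracellular matrix in astrocytes (adjusted p = 0.0336, adjusted p = 0.53 with an estimated correlation) were lower too. Uncalled in their own classes were Alzheimer disease risk (adjusted p = 0.489), amyloid precursor processing (0.236), heat shock (0.602), lysosome and autophagy (0.244), oxidative phosphorylation (0.753) and precursor proliferation (0.332), and endothelial barrier genes in every class.

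No gene passed the edgeR test for the interaction of vector and age. It called 0, with 2331 at unadjusted p under 0.05 and 7 called by DESeq2. Those 2331 too are fewer than unchanged genes would give. The smallest p-values are those of ADAMTS16 (3.65±0.59), VWC2L (3.45±0.61), GRB14 (4.42±0.81, adjusted p = 0.904 each) and TSHZ2 (6.85±1.32, adjusted p = 0.959) in astrocytes, and of DDX24, an RNA helicase, in excitatory neurons (1.27±0.25, adjusted p = 1). The 7 calls of DESeq2 are all higher, and without the filter on low counts edgeR called 30.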

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

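Groups of 3 libraries are too small for the test of a library standing apart, no interaction of vector and age passed, and no data outside the comparisons were used, so only patterns are weighed here. The tests of immune nuclei over 3 immune classes, of the UMI minimum and of the oligodendrocyte share were set before their results were seen, and all the other tests in this part only after.

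Interferon and antigen presentation genes were lower with age in all 7 classes. The members called lower make up 234 pairs of gene and class from 55 genes, with a median log2 fold of -3.30. They were picked for passing and for being lower, so their shared direction and the size of that median partly follow from the choice. Members without a call are left out of the tests below. For the called pairs, free RNA in the droplets as the whole cause is argued against, since the median is -3.08 with the plateau profile subtracted. That median covers 222 pairs, and 12 of the 234 were no longer tested after the subtraction. So are the libraries with under 50% of their UMIs in kept nuclei (median -3.14 without them). Without the libraries low in a class's own markers the median is -3.32. Classes in which no such library was left out are refitted on the same data, so that pooled median cannot decide. T or NK nuclei mixed into the other classes are argued against as well: in every class the members need at least 13.9 times the share of T or NK nuclei that their markers allow. Over the 3 immune classes tested, immune nuclei stay open as a candidate source, since the lowest such factor is 1.89, in granule neurons against perivascular macrophages (9.31% needed, 4.93% allowed), followed by 2.17 in excitatory neurons. Microglia need 4.21 and 4.42 times the allowed share in excitatory and granule neurons, which leaves them open there. All other pairs are above 5. Age, the difference named by the design, stays open as untested biology, as does any infection or immune state of the young animals. T or NK cells at 10.95% of young against 0.361% of aged libraries and the dividing cluster 8 at 2.39 and 1.42% in the young groups against 0.0648 and 0.0286% in the aged bear on that state, but no measurement of the animals is held.

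T or NK nuclei took a smaller share of aged libraries. A larger share of oligodendrocytes in aged libraries as the whole cause is argued against: among the other nuclei the share still differs by -13.44 percentage points (14.2±11.8% in young, 0.741±1.12% in aged, exact p = 0.025). The UMI minimum, which differs between libraries, stays open: with the highest minimum, 5825 UMIs, for all libraries the difference is -1.52 percentage points (exact p = 0.115), but only 57 of 1838 T or NK nuclei are left, 3.10%, so that test decides nothing. The minima themselves run against it in 5 of 6 aged libraries, at 379 to 1301 UMIs against 1187 to 5825 in young libraries, since a lower minimum keeps more small nuclei. BRI_aged 2, at 4264 UMIs, is the exception. How much blood or meninges each piece of tissue held was not measured, and age stays open as untested biology.

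Gene lists leaned higher or lower with Aβ under the preset correlation, in 63 pairs of list and class. Libraries low in a class's own markers are not settled as a cause. All 63 keep call and direction without them, but a class in which no library was left out is refitted on the same data. Its calls are kept by construction, so the count of 63 decides nothing over all classes. Free RNA stays open, since 31 of the 63 keep theirs with the plateau profile subtracted, and so do the libraries with under 50% of UMIs in nuclei, since 44 keep theirs without them. With an estimated correlation 0 of the 63 are called, and other splits of the libraries give as many, so no biological explanation is put forward.

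Other splits of the same 12 libraries show what a count can mean here. For age over both vectors, 2 of 45 splits, the real one included, gave as many genes as the real 2139, a share of 0.0444. The others were drawn at random from the possible splits, so that share is itself uncertain and chance is not excluded. The highest other gave 2652. That other split sets BRI_young 1 and 3, BRI_aged 2, Abeta_young 1 and 2 and Abeta_aged 1 against the rest, and points to a structure of the samples beside age. For Aβ over both ages and for the interaction, all 45 splits gave as many as the real 0, and the highest other gave 2692 for each, 709 of them in granule neurons. Any split gives at least 0, so these splits say nothing about a count of 0. For Aβ over both ages the highest sets BRI_young 1 and 3, BRI_aged 1 and 2, Abeta_young 2 and Abeta_aged 1 against the rest, and for the interaction it joins BRI_young 2, BRI_aged 1 and 2, Abeta_young 1 and 3 and Abeta_aged 1. These 2 are the same test, since they differ only in which side the young libraries are joined to. Its aged part sets BRI_aged 3, Abeta_aged 2 and Abeta_aged 3 apart, the libraries low in PROX1 and TRPC6 in granule neurons. The split of aged libraries with 2134 genes, given below, has the same sides. Outside granule neurons 1983 of the 2692 remain, a structure of the samples that neither age nor vector names. For gene lists chance is not excluded either: 25 of 45 splits gave at least the 63 calls for Aβ (highest other 120) and 8 of 45 at least the 93 for age (highest other 120). The splits of 3 against 3 libraries are too few for a share under 0.05: Aβ in young libraries 0 with 29 as the highest other (10 of 10 splits as large), Aβ in aged libraries 0 with 2134, 2093 of them in granule neurons (10 of 10), age in BRI libraries 76 with 39 (1 of 10) and age in Aβ libraries 936 with 41 (1 of 10).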

How the results depend on the processing

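Subtracting the plateau profile, leaving out the libraries with under 50% of UMIs in kept nuclei and leaving out those low in a class's own markers were chosen after seeing the data, and every other alternative before. Of the named genes with age over both vectors (122 pairs of gene and class, 2679 settings), 2362 values kept direction and side of the threshold, 262 lost the threshold, 51 gained it and 4 reversed. In BRI libraries 151 of 230 did so with 79 lost, and in Aβ libraries 157 of 230 with 73 lost. For Aβ over both ages 465 of 483 stayed, 5 gained and 13 reversed, and the single-age and interaction genes gave 108 of 115, 110 of 115 and 102 of 110, with none reversed.

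The number of genes depends on the tool and the filter. In the simulated data 12.3% of DESeq2 calls for age and 14.6% of those for Aβ were false. With edgeR the shares were 4.83 and 5.09%. For age over both vectors (2139) DESeq2 called 5789, no filter on low counts gave 3320, and RLE scaling, stricter nuclei, kept doublets, subtraction (1585), nuclei yield (1596) and own markers (2274) stayed within 1.5 times. In BRI libraries (76) DESeq2 called 851, no filter gave 343, subtraction 161 and the groups of the contrast alone 48. In Aβ libraries (936) DESeq2 called 3374, no filter gave 1986 and leaving out the libraries under 50% in nuclei 485. For Aβ (0 with edgeR) DESeq2 and no filter gave 4 and 49 over both ages, 13 and 50 in young and 20 and 48 in aged libraries, and 7 and 30 for the interaction. All other alternatives gave 0 there, apart from leaving out 1 library. With no filter, genes with few counts enter the fit, and which genes make up the added calls was not followed. The cause of these differences was not tested.

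Leaving out 1 library at a time assumes that a lone library would vary like the others. Age over both vectors gave 888 to 3707 genes: 888 without Abeta_aged 2, 895 without Abeta_aged 3, 1001 without Abeta_young 1, 1052 without BRI_aged 1, 1067 without BRI_young 3, 3304 without BRI_aged 2 and 3707 without Abeta_young 2. Age in BRI libraries gave 11 to 196: 11 without BRI_young 3 or BRI_aged 2, 12 without BRI_aged 1, 27, 48, 31 and 37 without Abeta_young 1 and Abeta_aged 1, 2 and 3, 155 without BRI_aged 3 and 196 without BRI_young 1. Age in Aβ libraries gave 93 to 1669: 93 without Abeta_aged 2, 122 without Abeta_aged 3, 163 without Abeta_young 1, 306 without Abeta_young 3, 1423 without Abeta_aged 1 and 1669 without Abeta_young 2. Aβ in aged libraries gave 0 to 12, the 12 without Abeta_aged 1, and Aβ over both ages, in young libraries and the interaction 0 throughout. The cause was not tested.

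For gene lists with age (93 pairs called) an estimated correlation left 11 and fry 41, while subtraction (62) and the rest stayed within 1.5 times, and leaving out 1 library gave 79 to 102. For Aβ (63) an estimated correlation and fry left 0 each and subtraction 33 (16 higher, 17 lower). Leaving out 1 library gave 28 (without Abeta_young 3) to 106 (without Abeta_young 2), and without BRI_young 1 the balance turned to 14 higher and 37 lower. For shares with age (3 classes) the centred log ratio called 6, and leaving out the libraries under 50% in nuclei 0 (smallest p 0.025 in 40 arrangements). The centred log ratio adds inhibitory neurons and microglia, higher with age, and B or plasma cells, lower. Leaving out 1 library gave 0 to 5, with 5 without BRI_young 1 or Abeta_young 2 and 0 without any of the other 10, where the 3 classes keep their direction at an adjusted p of 0.06 to 0.14 with 200 arrangements. Shares with Aβ gave 0 throughout.

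Single values that turned direction are these. MEF2C in oligodendrocytes with age is 0.16 with the plateau subtracted, and DCX in granule neurons -0.63 without libraries low in own markers. For Aβ, ITM2B in excitatory neurons is 0.22 without the libraries under 50% in nuclei and runs from -0.23 to 0.29 without 1 library (0.29 without BRI_young 3, 0.06 and 0.02 without BRI_aged 2 and 3, 0.09 and 0.02 without Abeta_young 2 and 3, 0.04 and 0.09 without Abeta_aged 2 and 3). APP runs from -0.15 to 0.06 (0.06 without BRI_young 3), GFAP in astrocytes from -0.17 (without BRI_young 1; -0.09 without Abeta_aged 2) to 0.59, and APOE in microglia from -0.22 (without Abeta_young 3; -0.02 without BRI_young 1) to 0.37. APP with age runs from -0.07 (without BRI_young 1; -0.02 without BRI_aged 1) to 0.15. None of these but MEF2C had passed. Where values lie near 0 a small move turns them, and the cause was not tested.

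The replicate numbers are shared between groups, and whether they pair the libraries is not settled. Over 105 pairs with the same number the deviations from the group means correlate at a median of 0.003 (-0.784 to 0.745, 43 pairs over 0.1), against -0.011 in 212 pairs with different numbers, and 35 of 77 libraries and classes correlate best with their own number, which about 1 in 3 partners shares (7 of 11 in each of the 3 neuron classes). With the replicate block, age over both vectors gave 1331 genes, age in BRI libraries 43, age in Aβ libraries 530, and every Aβ contrast and the interaction 0. List calls were 74 for Aβ and 83 for age, and the sign-flip test over pairs called 0 shares with age, since its smallest p is 0.03125.

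Depth limits the shares. The UMI minimum runs from 379 to 5825, so small nuclei are counted in some libraries and lost in others, and classes with few nuclei drop libraries from the gene tests.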

Other observations

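Some clusters stayed unnamed and enter no test of genes, lists or named classes. Only their own shares are compared, here and for cluster 8 also above. Cluster 8, led by the cell division genes TOP2A and MKI67, held 385 nuclei: 2.39±2.61% of nuclei in BRI_young, 0.0648±0.0579% in BRI_aged, 1.42±0.2496% in Abeta_young and 0.0286±0.0411% in Abeta_aged (exact permutation p = 0.005 for age, the smallest the test can give, without adjustment). Cluster 30, led by the plasma cell genes JCHAIN and MZB1, held 2247 nuclei at 0.378±0.211, 0.0949±0.135, 8.63±14.2 and 0.0640±0.0715% in the same order, where Abeta_young runs from 0 to 25.01% and rests on 1 library (exact permutation p = 0.05). Cluster 31, with IRF4, POU2AF1 and XBP1 on top, held 1691 nuclei at 2.81±2.825, 0.485±0.734, 5.53±5.67 and 0.131±0.0698% (exact permutation p = 0.065). Cluster 18, with FAM149A, VWF and C3, held 2306 nuclei at 6.07±6.85, 3.17±5.38, 7.82±7.035 and 0.0583±0.0374% (exact permutation p = 0.1). HS3ST4 and RXFP1 lead both cluster 9 (2242 nuclei; 7.50±6.37, 3.78±2.85, 5.06±2.34 and 1.23±0.909%; exact permutation p = 0.075) and cluster 21 (761 nuclei; 0.599±0.587, 1.39±0.505, 0.151±0.144 and 1.81±0.657%; exact permutation p = 0.01).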
